A study of Mus musculus with 4 samples.

How the data were processed

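RNA from RPP631 mouse SCLC cells kept for 48 h in DMSO or in 100 nM YKL was sequenced in bulk, with 2 libraries in each group. Reads were aligned to mm10 with STAR 2.5.2b and assigned to genes with featureCounts, per the submitters' processing notes. The deposited table holds raw counts per gene and library for 54232 genes, with no other per-sample column. The authors also deposited a table of their own DESeq2 comparison, with a normalized mean signal, a log2 fold change, its error, a test score, a p-value and an adjusted p-value for each of 15936 genes. That deposited table was used only for comparison, after 28 entries with an ambiguous gene name were dropped. The sources used here do not give the strand setting of the counting, so reads of genes with overlapping exons on opposite strands may have been joined or split. Positions and exon overlaps were taken from the deposited count table and biotypes from the deposited gene annotation. Of the gene identifiers, 99.72% were found in GENCODE M21 (GRCm38), which served as a check and gave the GC content of transcripts.

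Differences between YKL and DMSO were tested on the raw counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood test with a robust prior was applied with 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are given as TMM-scaled CPM, mean ± SD of 2 libraries, and log2 fold changes are YKL over DMSO with standard errors. Each standard error was derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. For each of 20 gene lists the members called were counted with adjustment over all genes and over the list alone. Each list was tested as a whole with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera rests on the 2 residual degrees of freedom and has little power here. A list not called by it is therefore no evidence against a shift of that list.

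The total of assigned counts was 34189709 and 31082753 in the DMSO libraries and 29817387 and 32956564 in the YKL libraries. The common biological coefficient of variation was 25%. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples. Between the libraries of a pair, the chi-square per degree of freedom was 87.8 for DMSO and 37.5 for YKL, over genes with a summed count of at least 20. The procedure was tested on simulated data for YKL against DMSO in 5 runs with a median of 16345 genes, of which 200 were changed 2-fold or 4-fold. Sets of 40 genes shifted 1.5-fold came on top of these. Another number of changed genes could give other shares of false calls. There, edgeR recovered 27.6% of the genes changed 2-fold and 73.3% of those changed 4-fold, and 11.3% of its calls were false. DESeq2 recovered 40.6% and 77.3%, with 23% of its calls false. Camera called 10 of 10 sets of 40 genes shifted 1.5-fold and 0 of 90 unshifted sets. The simulated genes were drawn independently of each other, so these counts cannot show how camera treats lists of correlated genes. In the real lists the estimated correlation ran from -0.0474 for nucleic acid sensing to 0.862 for glycolysis and hypoxia. It was 0.612 for G2/M and mitosis and 0.567 for ribosomal proteins.

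The gene lists, the tests, the alternatives and the rule for naming genes were written before the data were examined, apart from those described as chosen later. The rule named Cdk7, Rb1, Rbl2 and Trp53, and the 6 largest increases and 6 largest decreases among called protein-coding genes with a mean of at least 5 CPM and both YKL libraries on the same side of both DMSO libraries. It also named, in each list, the 2 called members with the smallest p in the direction with more calls and the 1 in the other direction, or the 2 most abundant members of a list with no call. Tnf, Cxcl9, Cxcl10 and Ccl5 were named whatever their result. Some called members of the lists are not reported here. With 2 libraries per group only 3 splits of the samples exist, so the labels were not permuted. The alternatives were RLE, total count and upper quartile scaling, no filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, no robust prior, protein-coding genes alone, each library left out in turn, the DESeq2 1.42.0 Wald test, an adjusted p under 0.01, and glmTreat against a 1.2-fold change. Figures were drawn with matplotlib.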

Results

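The transcriptome of RPP631 cells, a mouse small cell lung cancer (SCLC) line, was measured by bulk RNA sequencing after 48 h in DMSO, the vehicle, or in 100 nM YKL, a compound that the title of the series describes as an inhibitor of CDK7. CDK7 is the kinase of the general transcription factor TFIIH and also activates the kinases that drive the cell cycle. The comparison asked how transcript levels in these tumour cells respond to the inhibitor. Each group held 2 libraries. The libraries DMSO replicate 1 and DMSO replicate 2 had 34189709 and 31082753 counts assigned to genes, and YKL replicate 1 and YKL replicate 2 had 29817387 and 32956564. Of the 54232 genes in the table, 24166 had no count in any library and 16749 passed the filter on low counts and were tested. The first principal component of log2 CPM carried 52.4% of the variance and separated YKL from DMSO, whereas the second carried 30.7% and set the DMSO libraries apart from each other, at scores of 37.2 and -51.8. Mitochondrially encoded transcripts took 1.01% and 1.14% of the counts in the DMSO libraries and 1.25% and 1.78% in the YKL libraries.

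Exposure to YKL was accompanied by lower relative levels of 242 genes, among them Ube2c, Cdc20, Aldh18a1 and Rpl17. Relative levels were higher for 351 genes that included Cdkn1a, Ccne1 and Polr2a. Scaling sets the middle of all fold changes near 0 (median log2 fold change -1e-04). A rise or fall shared by most transcripts would therefore not show in these values. The largest increase among the well expressed protein-coding genes was that of Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331, mm10), which encodes the transcription factor T-bet. It rose 17.6-fold, from 0.595 ± 0.46 CPM in DMSO to 10.5 ± 1 CPM in YKL (mean ± SD, n = 2 in each group; log2 fold change 4.14 ± 0.58, standard error; adjusted p = 0.0112). Pmel, a melanosome gene on chromosome 10 (128704195 to 128720238), rose 9.52-fold from 1.89 ± 0.471 to 18 ± 5.29 CPM (adjusted p = 0.00795), but its exons overlap those of Cdk2 and Dgka on the other strand. Etv4, an ETS transcription factor that is induced by ERK signalling, rose from 4.77 ± 0.789 to 30.5 ± 8.71 CPM (log2 fold change 2.68 ± 0.31), and Clec2l rose from 13.5 ± 2.72 to 78.8 ± 7.20 CPM (2.54 ± 0.22). The amino acid transporter gene Slc43a1 had a log2 fold change of 2.79 ± 0.45, and 4930524J08Rik one of 2.92 ± 0.43. The largest decrease was that of Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), which encodes the cystine transporter. It fell 6.31-fold, from 13.7 ± 3.97 to 2.16 ± 0.0584 CPM (log2 fold change -2.66 ± 0.38, adjusted p = 0.0112). The neuropeptide Y receptor gene Npy1r fell from 75.1 ± 42.0 to 12.6 ± 1.15 CPM (adjusted p = 0.035). Brd3os, D430019H16Rik, Vwa5b1 and P2rx3, whose exons overlap Ssrp1, completed the set of largest decreases, with log2 fold changes of -2.50, -2.47, -2.27 and -2.34.

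In total, edgeR's quasi-likelihood test called 593 genes at a Benjamini-Hochberg adjusted p under 0.05, 351 of them higher and 242 lower in YKL. A change of at least 2-fold was met by 425 of these, 260 higher and 165 lower. In each of the 593 genes both YKL libraries lay on the same side of both DMSO libraries, an arrangement found in 52.3% of the genes tested and in 33.3% by chance. The count is tied to the processing and to single libraries: DESeq2 called 1588 genes, edgeR with scaling by total count alone 169, with upper quartile scaling 331, without the filter 1740 and without the robust prior 236. With 1 library left out, edgeR called more genes without either DMSO library and fewer without either YKL library. None of the called genes that were tested again, at least 589 of the 593 in each of these fits, changed sign there. That outcome was nearly fixed in advance by the separation of the groups in each called gene. Of the 37 named genes that were called, 7 were called in all 13 refits, namely Tbx21, Pmel, Etv4, Clec2l, Ube2c, Cdc20 and Aldh18a1. Many others lost their call without YKL replicate 1 or YKL replicate 2. In those fits the spread comes from the DMSO pair alone, which differed more (chi-square per degree of freedom 87.8 against 37.5 for the YKL pair). A call can therefore end while the effect stays. Cdkn1a had log2 fold changes of 1.43 and 1.35 there, against 1.39 with all libraries, whereas Hes1 had 0.89 and 1.54 against 1.25.

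**Figure D1:**
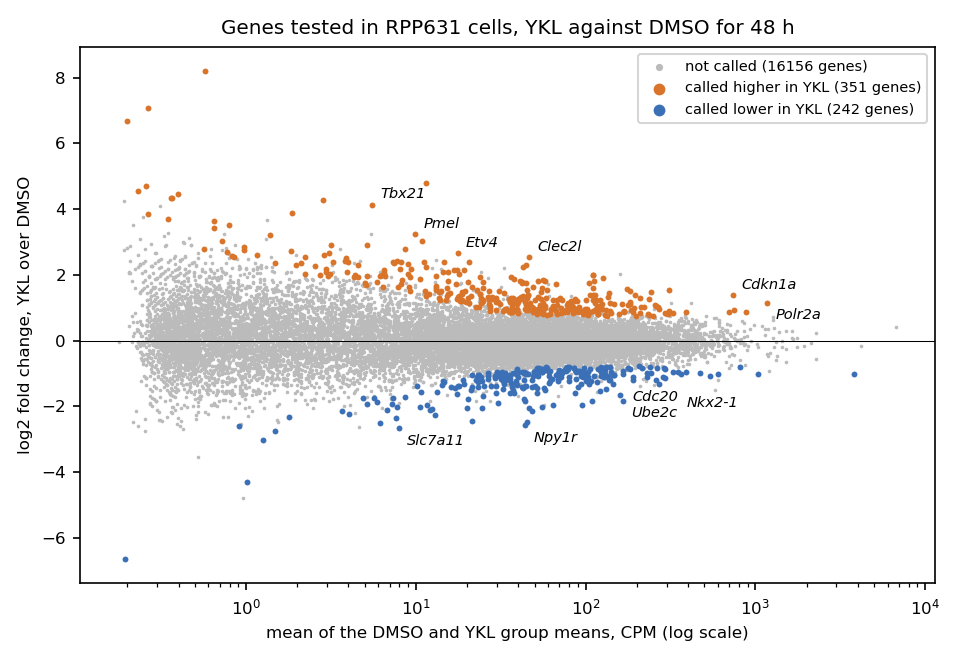
Log2 fold change of YKL over DMSO (vertical axis) against mean level (CPM, horizontal log axis) for the 16749 genes tested. Orange points are the 351 genes called higher and blue points the 242 called lower in YKL at an edgeR adjusted p under 0.05, and grey points were not called.

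Part of the transcripts of the late cell cycle fell. Of 49 tested genes for G2/M and mitosis, 18 were lower and 1 was higher in YKL, and 30 were lower and 1 higher when adjusted over the list alone. The median log2 fold change was -0.78 and 46 of the 49 values were below 0. Ube2c (ENSMUSG00000001403), the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell 3.55-fold from 260 ± 45.8 to 73.2 ± 6.48 CPM (adjusted p = 0.00795), and Cdc20, an activator of that complex, fell 3.15-fold from 242 ± 64.3 to 76.8 ± 2.27 CPM (adjusted p = 0.0102). Both genes share exonic bases with a gene on the other strand, Tnnc2 and Elovl1. Among the other lower members, named after their values were seen, were Cenpa, Bub1, Kif11, Ccnb2, Aurkb, Plk1 and Foxm1, at log2 fold changes of -1.84, -1.41, -1.33, -1.53, -1.03, -1.06 and -1.01. The member that rose was Mybl2, a transcription factor expressed from the G1/S boundary, from 95.6 ± 9.18 to 165 ± 1.83 CPM (adjusted p = 0.0469), a call that ended with total count or upper quartile scaling, without the robust prior and without DMSO replicate 2, YKL replicate 1 or YKL replicate 2. The camera test placed the list below other genes at an adjusted p = 3.59e-25, but at an adjusted p = 0.56 with an estimated correlation between its genes. That alternative has 2 residual degrees of freedom and called 0 of the 20 lists, so it could hardly have called this list. Instead of 19 members, 11 and 2 were called without YKL replicate 1 or YKL replicate 2, 33 without DMSO replicate 2, 29 without the filter and 28 by DESeq2.

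Genes for DNA replication and the G1/S transition were mostly not called. Of 52 tested, 3 rose and none fell, or 4 and none when adjusted over the list alone, with a median log2 fold change of 0.24. Ccne1, which encodes cyclin E1, rose 2.08-fold from 78.4 ± 0.887 to 163 ± 15.8 CPM (adjusted p = 0.0217) and the replication licensing gene Cdc6 rose 1.91-fold from 128 ± 2.46 to 244 ± 13.9 CPM (adjusted p = 0.0273). The list stood above other genes by camera (adjusted p = 0.025), but not with an estimated correlation (adjusted p = 0.691), nor without DMSO replicate 2 (adjusted p = 0.513) or without YKL replicate 2 (adjusted p = 0.116). Of 41 genes of the DNA damage checkpoint and repair, only Fancd2 was called, which fell from 55.4 ± 2.14 to 28.5 ± 1.05 CPM (adjusted p = 0.0322) and shares exonic bases with Fancd2os. Adjusted over the list alone 4 were higher and 1 lower, and the list as a whole was not called (adjusted p = 0.465). Without the filter 6 of these repair genes were called, and with total count scaling 0. Of 17 genes for G1 cyclins, CDKs and their inhibitors, 2 rose, both of them CDK inhibitors. Cdkn1a, which encodes p21, went from 409 ± 129 to 1070 ± 37.1 CPM (2.62-fold, adjusted p = 0.0219) and Cdkn1c, which encodes p57, from 102 ± 3.21 to 181 ± 18.5 CPM (adjusted p = 0.0399), the latter overlapping the antisense gene Gm44732. Adjusted over the list alone 6 were higher and 2 lower, and the list's median of -0.26 and its camera direction, up, differed in sign (adjusted p = 0.245). Of 37 genes with symbols of the replication-dependent histones, 3 rose, or 6 with 2 lower when adjusted over the list alone. Transcripts of this class mostly lack a poly(A) tail, so their levels also depend on the library type. Hist1h1c went from 27.3 ± 6.60 to 82.7 ± 32.8 CPM, Hist2h3c2 from 0.277 ± 0.0117 to 5.42 ± 2.96 CPM, and Hist2h2be, named after its value was seen, had a log2 fold change of 0.86. Reads of such near-identical copies can be split between genes, and the histone share of all counts was 0.0204% and 0.0167% in DMSO and 0.0236% and 0.034% in YKL. The histone list was not called (adjusted p = 0.245), but was called up without DMSO replicate 1 (adjusted p = 0.0107) and without YKL replicate 1 (adjusted p = 0.00815), and its direction turned without DMSO replicate 2 or without YKL replicate 2 (adjusted p = 0.597 and 0.301).

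**Figure D2:**
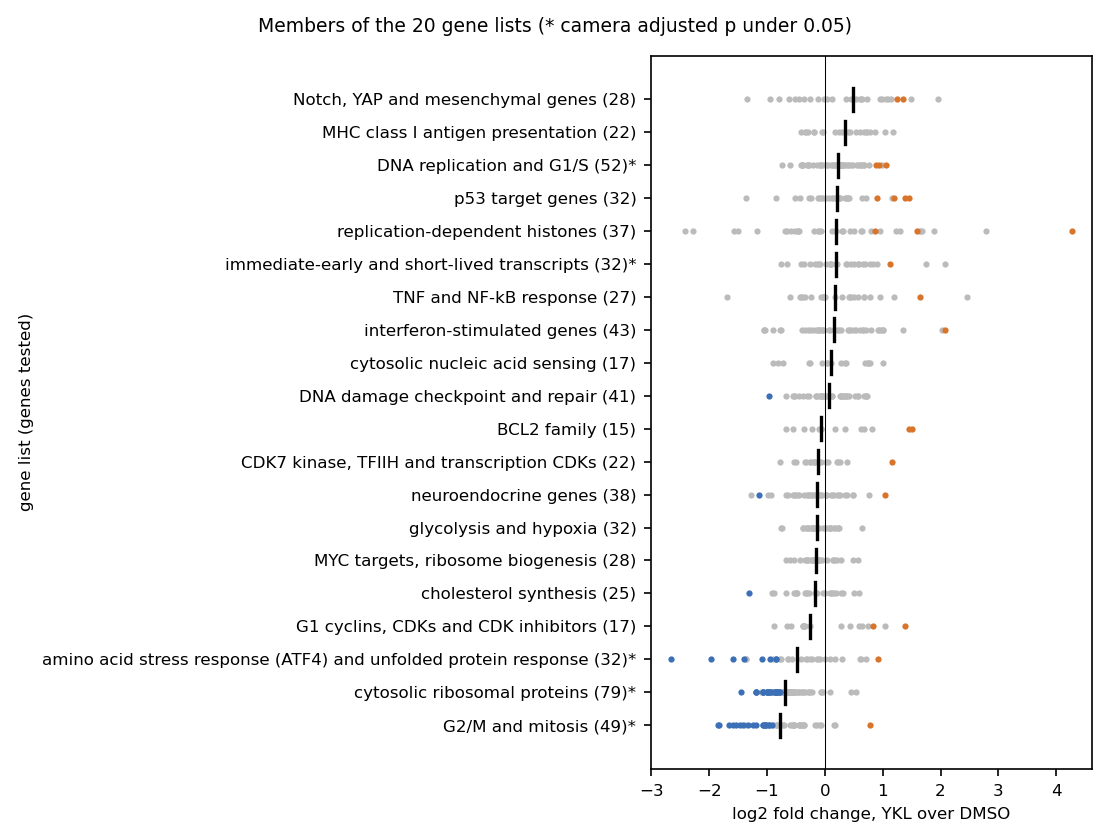
Log2 fold change of YKL over DMSO (horizontal axis) for each tested member of the 20 gene lists (vertical axis, number of genes tested in parentheses), ordered by the list's median, which a black bar marks. Orange and blue points are members called higher and lower, grey points were not called, and an asterisk marks the 5 lists called by camera with its preset correlation. The lists for G2/M and mitosis and for ribosomal proteins have the lowest medians, -0.78 and -0.68.

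A few genes that respond to p53 rose. Of 32 tested targets 4 were higher and none lower, and 4 were higher and 2 lower when adjusted over the list alone. Besides Cdkn1a these were Tigar, a regulator of glycolysis that went from 18.2 ± 0.192 to 41.5 ± 1.25 CPM and overlaps the antisense gene Platr31, Pmaip1, which encodes the BH3-only protein Noxa and went from 17.7 ± 6.21 to 48.2 ± 3.08 CPM, and Trp53inp1, named after its value was seen, with a log2 fold change of 0.91. The list was not called (adjusted p = 0.0764), except without DMSO replicate 2 (adjusted p = 0.0418). Trp53 itself had 17.5 ± 3.57 CPM in DMSO and 17.7 ± 7.06 CPM in YKL, and neither Rb1 (29.9 ± 4.78 and 34.1 ± 10.6 CPM) nor Rbl2 (3 ± 0.962 and 5.25 ± 0.658 CPM) was called. SCLC lines of the RPP type commonly derive from mice in which these genes were deleted in the lung, but the labels do not give the genotype of RPP631 and gene-level counts do not show which exons were read. Of 15 genes of the BCL2 family, 2 pro-apoptotic members rose, Pmaip1 and Hrk, the latter from 5.93 ± 0.772 to 16.7 ± 5.99 CPM (adjusted p = 0.0476). The call of Hrk ended with total count or upper quartile scaling, with the stricter filter, without the robust prior, among protein-coding genes alone and without YKL replicate 1 or YKL replicate 2, and that of Pmaip1 with total count scaling, without the robust prior and without either YKL library. Adjusted over the list alone 5 were higher and none lower, and the median of -0.06 and the camera direction, up, differed in sign (adjusted p = 0.245).

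Lists for inflammatory signalling held few called genes with all libraries. Without the filter 5 interferon-stimulated genes and 3 of the TNF and NF-kB response were called. So were 3 of MHC class I presentation and 4 of nucleic acid sensing. By DESeq2 these counts were 3, 3, 3 and 4. Both fits also called more genes in all, 1740 and 1588 against 593. More members were called without DMSO replicate 2 as well, a fit in which calls over all genes also rose. Of 43 interferon-stimulated genes 1 rose, or 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.299). The called gene was Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), which encodes a chemokine that attracts T cells. It had 111 and 52 counts in DMSO replicates 1 and 2 and 407 and 245 counts in YKL replicates 1 and 2, or 2.48 ± 1.18 and 10.4 ± 4.01 CPM (4.19-fold, adjusted p = 0.0474). Its exons overlap those of Art3, and its call ended with total count or upper quartile scaling, with the stricter filter, without the robust prior, among protein-coding genes alone and without YKL replicate 1 or YKL replicate 2. The other immune mediators checked in every library were near the floor. Tnf had 1 and 0 counts in DMSO and 10 and 1 in YKL, Ccl5 had 1 and 0 in DMSO and 3 and 1 in YKL, and Cxcl9 had 0 and 1 in DMSO and 0 and 0 in YKL, so a difference was not testable at this depth. Of 27 genes of the TNF and NF-kB response 1 was called, also when adjusted over the list alone, namely Plau, which encodes urokinase and rose from 10.5 ± 3.86 to 32.6 ± 7.88 CPM (adjusted p = 0.032). Its call ended with total count or upper quartile scaling, without the robust prior and without YKL replicate 1 or YKL replicate 2. The list was not called (adjusted p = 0.245), except without DMSO replicate 2 (adjusted p = 0.0344). None of 22 genes of MHC class I antigen presentation was called, and 2 were higher when adjusted over the list alone. The abundant chaperone genes Canx and Pdia3 had log2 fold changes of 0.30 ± 0.18 and 0.44 ± 0.18. At an adjusted p = 0.0742 the list missed the threshold, which it passed without DMSO replicate 2 (adjusted p = 0.0275), without YKL replicate 2 (adjusted p = 0.00861) and without the filter (adjusted p = 0.0306). Of 17 genes for cytosolic nucleic acid sensing none was called and 2 were higher and 2 lower when adjusted over the list alone (list adjusted p = 0.555). Samhd1 went from 79.8 ± 7.35 to 135 ± 19.4 CPM (adjusted p = 0.0635) and Rnaseh2b from 88.8 ± 24.1 to 53.9 ± 0.266 CPM (adjusted p = 0.1). Both were called by DESeq2, without the filter and with the replicate number as a block.

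Among 22 genes for CDK7 and its partners, TFIIH and other transcription CDKs, 1 rose, also when adjusted over the list alone. This was Polr2a (ENSMUSG00000005198, chromosome 11, 69733997 to 69758637), which encodes the largest subunit of RNA polymerase II. It rose 2.24-fold, from 723 ± 4.54 to 1620 ± 200 CPM (adjusted p = 0.0197), and the list was not called (adjusted p = 0.487). Cdk7 (ENSMUSG00000069089, chromosome 13, 100702631 to 100730939) had 708 and 549 counts in DMSO replicates 1 and 2 and 336 and 373 counts in YKL replicates 1 and 2. Its level of 19.3 ± 2.65 CPM in DMSO and 11.3 ± 0.433 CPM in YKL (log2 fold change -0.78 ± 0.27) was not called (adjusted p = 0.138), except by DESeq2 and without DMSO replicate 2. Of 32 immediate-early and short-lived transcripts 1 rose, or 3 with 1 lower when adjusted over the list alone. The called gene, the early response factor Klf10, went from 78.1 ± 4.50 to 171 ± 8.54 CPM (2.19-fold, adjusted p = 0.0173). The list stood above other genes by camera (adjusted p = 0.0265), but was not called without DMSO replicate 2 or without YKL replicate 2. Nor was it called by camera with an estimated correlation (adjusted p = 0.56). The correlation estimated for this list, -0.00167, was below the preset 0.01, so correlation does not account for that loss.

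**Figure D3:**
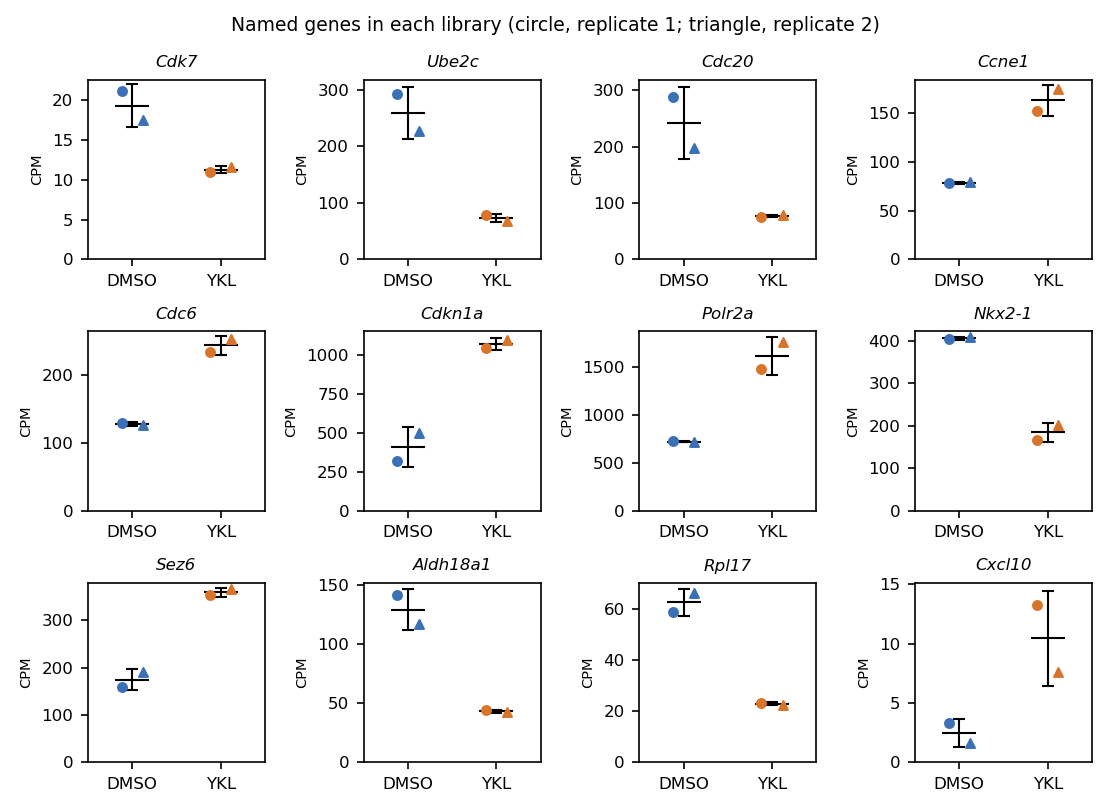
Levels of 12 named genes (CPM, vertical axes from 0) in DMSO (blue) and YKL (orange). Circles are replicate 1, triangles replicate 2, and the horizontal line and error bar are the mean ± SD of the 2 libraries. The YKL libraries lie below both DMSO libraries for Cdk7, Ube2c, Cdc20, Nkx2-1, Aldh18a1 and Rpl17 and above them for Ccne1, Cdc6, Cdkn1a, Polr2a, Sez6 and Cxcl10. Of these genes only Cdk7, at means of 19.3 and 11.3 CPM in DMSO and YKL, was not called.

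Markers of the neuroendocrine state were mostly not called with all libraries. Of 38 tested, 1 rose and 1 fell, or 2 and 3 when adjusted over the list alone, with a median log2 fold change of -0.13 (list adjusted p = 0.176, and 0.0133, down, without DMSO replicate 2). Nkx2-1, a lung lineage transcription factor, fell 2.20-fold from 406 ± 3.25 to 184 ± 23.4 CPM (adjusted p = 0.0189), and the neuronal gene Sez6 rose 2.05-fold from 175 ± 22.7 to 359 ± 8.88 CPM (adjusted p = 0.0234). Without the filter 7 neuroendocrine members were called and by DESeq2 6, and the list for Notch, YAP and mesenchymal genes had 5 and 4. Both fits also called more genes in all, 1740 and 1588 against 593. In both lists more members were called without DMSO replicate 2 too, where calls over all genes also rose. Of 28 Notch, YAP and mesenchymal genes 2 rose, or 4 when adjusted over the list alone, and none fell. The receptor tyrosine kinase gene Epha2 went from 11.9 ± 1.59 to 30.3 ± 3.41 CPM (adjusted p = 0.026) and the Notch target Hes1 from 10.7 ± 1.37 to 25.6 ± 8.11 CPM (adjusted p = 0.04999). The call of Hes1 ended in the same 7 refits as that of Cxcl10. With a median of 0.49 this list was not called (adjusted p = 0.0764), but was called without DMSO replicate 2 (adjusted p = 0.0284) and without YKL replicate 2 (adjusted p = 0.00484).

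Some genes induced by ATF4, the transcription factor of the amino acid stress response, fell. The list that joined them with genes of the unfolded protein response had 32 tested members, of which 8 were lower and 1 was higher, or 13 and 4 when adjusted over the list alone, with a median log2 fold change of -0.49. Besides Slc7a11, Aldh18a1 of proline synthesis fell 2.99-fold from 129 ± 17.2 to 43.2 ± 1.42 CPM (adjusted p = 0.00795). The other lower members, named after their values were seen, were Phgdh, Chac1, Asns, Trib3, Shmt2 and Atf5, with log2 fold changes of -1.97, -1.39, -1.09, -0.95, -0.84 and -0.84. The higher one was Sdf2l1, a chaperone component of the endoplasmic reticulum, at 59.8 ± 4.05 and 113 ± 12.4 CPM. A split of the list made after seeing the values gave a median of -0.84 for its 21 members of amino acid metabolism and ATF4 signalling, all of them below 0, and of 0.18 for its 11 members of the unfolded protein response. The list was called by camera (adjusted p = 8.08e-06), but not with an estimated correlation (adjusted p = 0.56). Instead of 9 members, 2 and 1 were called without YKL replicate 1 or YKL replicate 2, 16 without DMSO replicate 2 and 17 without the filter.

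Part of the transcripts of cytosolic ribosomal proteins fell. Of 79 tested, 24 were lower and none was higher, or 56 and none when adjusted over the list alone, and 76 values were below 0, with a median log2 fold change of -0.68. The calls were spread over both subunits, with 12 of 31 Rps genes and 12 of 47 Rpl genes. Rpl17 went from 62.8 ± 5.24 to 23 ± 0.522 CPM (2.73-fold, adjusted p = 0.0105). The median per library, relative to each gene's mean over all libraries, was 0.29 and 0.41 in DMSO replicates 1 and 2 and -0.50 and -0.21 in YKL replicates 1 and 2. Under the other scalings the median of the fold changes lay between -0.66 and -0.70. The list was called by camera (adjusted p = 7.9e-29), but not with an estimated correlation (adjusted p = 0.56), and it stayed called with any library left out. Of its genes 1 and 0 were called without YKL replicate 1 or YKL replicate 2, 41 and 40 without DMSO replicate 1 or DMSO replicate 2, 48 by DESeq2 and 49 without the filter. Of 28 MYC targets for ribosome biogenesis none was called, also when adjusted over the list alone. Ncl and Npm1 had log2 fold changes of 0.15 ± 0.22 and -0.29 ± 0.18 (list adjusted p = 0.245, and 0.00379, down, without DMSO replicate 2).

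Metabolic lists depended on single control libraries. Of 25 genes in the list for cholesterol synthesis, 1 fell, or 2 when adjusted over the list alone. The list was not called (adjusted p = 0.245), but was called down without DMSO replicate 1 (adjusted p = 1.2e-05), and its direction turned without DMSO replicate 2 (adjusted p = 0.356). None of 32 genes for glycolysis and hypoxia was called, also when adjusted over the list alone, since the DMSO libraries differed more from each other than from YKL. Ldha had 25300 counts in DMSO replicate 1 and 104236 in DMSO replicate 2, against 50002 and 65057 in the YKL libraries, and Pkm had a log2 fold change of 0.24 ± 0.26. The median of this list, -0.14, and its camera direction, up, differed in sign (adjusted p = 0.729). Without DMSO replicate 1 the list was called down (adjusted p = 1.35e-18), and without DMSO replicate 2 it was called up (adjusted p = 1.16e-30), with 17 and 24 members called.

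Markers of other cell types that a culture could hold were low. The summed CPM of 15 immune genes was 11.0 ± 3.64 in DMSO and 16.7 ± 3.09 in YKL, that of 12 stromal genes 27.9 ± 4.25 and 53 ± 37.5, that of 9 endothelial genes 5.67 ± 0.826 and 9.37 ± 5.12, that of 12 lung epithelial genes 23.2 ± 2.18 and 36.8 ± 0.988, and that of 5 red blood cell genes 0.491 ± 0.0664 and 0.571 ± 0.115. The most abundant gene of each set was Cd74, Pdgfra, Flt1, Hopx and Alas2, at means of 4.4, 23.8, 3.50, 16.8 and 0.468 CPM over all libraries. The only called marker was the leukocyte gene Ptprc, named after its values were seen, with 0 and 2 counts in DMSO and 25 and 23 in YKL.

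The authors' deposited table of their own comparison lists 15936 genes, of which 4428 pass an adjusted p under 0.05, 2211 higher and 2217 lower in YKL. DESeq2 run here on the deposited counts called 1588, and the settings behind the larger number are not given in the sources used here. Of the 593 genes called by edgeR, 585 could be matched to the authors' deposited table, and 585 pass there with the same sign. They make up 13.2% of the passing genes that could be matched. Across genes, which are not independent replicates, the log2 fold changes in the authors' deposited table and those of edgeR had a Pearson correlation of 0.962 with a slope of 0.726, so those in the table lie nearer to 0. In the authors' deposited table Cdk7 has a log2 fold change of -0.73 (adjusted p = 0.00029) and Cdkn1a one of 1.31 (adjusted p = 1.74e-13).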

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

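None of the 593 called genes changed sign in the 13 refits where it was tested again (545 with the filter of 5 CPM, 550 among protein-coding genes, 589 or more in the others). This was nearly fixed in advance, since in each called gene both YKL libraries lay on the same side of both DMSO libraries. The number called depended on the processing. RLE scaling (701 genes), the filter of 5 CPM (563) and protein-coding genes alone (512) kept it within 1.5 times. Genes called, YKL against DMSO, were 169 with total count scaling (98 higher, 71 lower, 161 at least 2-fold), 331 with upper quartile scaling (201, 130, 262), 1740 without the filter (905, 835, 926), 236 without the robust prior (140, 96, 229), 1588 with DESeq2 (825, 763, 731), 30 at an adjusted p under 0.01 (21, 9, 30) and 271 by glmTreat. With 1 library left out, when the lone library is assumed to vary like the other group, between 71 and 2453 genes were called, 52 to 1393 higher, 19 to 1060 lower and 71 to 1502 at least 2-fold. The share of higher calls was 59.2%, with 56.9% to 60.7% under other scalings, 52% with DESeq2 and without the filter, 73.2% without YKL replicate 2 and 49.6% without DMSO replicate 1, where lower calls were the majority. The cause was not tested.

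The libraries share replicate numbers, but the labels do not state a pairing, and the deviations of same-numbered libraries had a correlation of 0.152 over only 2 pairs. The shifts of the 20 chromosomes between replicate numbers had a correlation of 0.955 between the groups, a hint from the data and not the design. With the replicate number as a block, edgeR called 1387 genes (785 higher, 602 lower, 745 at least 2-fold). Among the named genes, the call of D430019H16Rik ended with the block (adjusted p = 0.101), and Samhd1 (adjusted p = 0.0245) and Rnaseh2b (adjusted p = 0.0441) were called. The block placed the Notch, YAP and mesenchymal list at an adjusted p = 0.0439 and gave Trp53 and Ldha log2 fold changes of -0.028 and 0.199. The block with the DESeq2 Wald test, chosen after seeing the data, called 1311 genes (705, 606, 690).

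The lists for G2/M and mitosis (adjusted p from 6.92e-35 to 1.65e-16), ribosomal proteins (2.9e-35 to 3.25e-14) and ATF4 and the unfolded protein response (9.06e-08 to 0.000127) stayed called, in the same direction, by camera with each library left out. With an estimated correlation no list was called, at an adjusted p = 0.691 for DNA replication and G1/S and 0.56 for G2/M, immediate-early transcripts, ATF4 and ribosomal proteins. With fry these were 0.302, 0.183, 0.154, 0.154 and 0.183. Camera with an estimated correlation has 2 residual degrees of freedom and little power, so its lost calls do not show that correlation between genes made the calls. MHC class I was called without the filter (0.0306) and histones with the filter of 5 CPM (0.0103). With each library left out, the adjusted p ran from 7.24e-05 to 0.513 for DNA replication, 0.0418 to 0.181 for p53 targets, 0.0344 to 0.471 for TNF, 0.00861 to 0.255 for MHC class I, 0.0133 to 0.453 for neuroendocrine genes, 0.00484 to 0.462 for Notch and 0.00703 to 0.153 for immediate-early transcripts. It ran from 1.2e-05 to 0.614 for cholesterol synthesis, 1.16e-30 to 0.794 for glycolysis, 0.00379 to 0.813 for MYC targets and 0.00815 to 0.597 for histones, and each of these 4 lists turned direction in at least 1 of these fits. The cause was not tested.

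The members called ranged over the 13 refits from 0 to 8 for DNA replication, DNA damage, p53, MHC class I and Notch, 2 to 33 for G2/M, 0 to 9 for interferon and neuroendocrine genes, 0 to 6 for TNF, G1 CDKs and immediate-early transcripts, 0 to 4 for nucleic acid sensing, 0 to 3 for CDK7 and MYC targets, 1 to 17 for ATF4, 0 to 5 for BCL2, 0 to 7 for cholesterol synthesis, 0 to 24 for glycolysis, 0 to 10 for histones and 0 to 49 for ribosomal proteins. Of the 37 named genes called, 16 lost the call with total count scaling, 7 with upper quartile scaling and 11 without the robust prior. Besides losses without a YKL library, P2rx3 and Cdkn1c lost the call with total count or upper quartile scaling and without the robust prior, Fancd2, Sdf2l1 and Hist1h1c with total count scaling and without the robust prior, and Brd3os, Slc43a1, Cdkn1a and Epha2 with total count scaling. No named gene called with all libraries turned sign, an outcome nearly fixed by the separation of the groups in called genes. Ldha, not called with all libraries, was called lower without DMSO replicate 1 (adjusted p = 0.0436) and higher without DMSO replicate 2 (adjusted p = 0.000179). Trp53, also without a call, went to -0.011 without the filter, and with each library left out the log2 fold changes ran from -0.46 to 0.37 for Trp53, -0.089 to 0.635 for Pkm, -0.86 to 1.24 for Ldha, -0.13 to 0.44 for Ncl and -0.17 to 0.48 for Rb1. At the depth of these libraries, Tnf, Cxcl9 and Ccl5 stayed at 10 counts or fewer and were not testable.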

Other observations

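The genes and lists in this part were chosen only after their results were seen, and adjusted p-values are those of edgeR over all genes. Of 15 regulators of multiciliation, 3 rose and 4 had log2 fold changes below 0. Deup1 rose from 6.57 ± 0.855 CPM in DMSO to 34.8 ± 10.6 CPM in YKL (adjusted p = 0.00795), Ccno from 14.9 ± 6.70 to 74.1 ± 4.10 CPM (adjusted p = 0.0135) and Mcidas from 3.96 ± 1.54 to 18.8 ± 3.43 CPM (adjusted p = 0.019). Foxj1, at a log2 fold change of 1.13, was not called (adjusted p = 0.107). None of 17 tested axoneme genes was called, and 12 of them lay below 0. These lists were drawn up because of the called genes, so a test of each list as a whole carries no weight and its p-value is left out. Of 16 ERK and FGF feedback genes Etv4, Epha2 and Etv5 rose, the last from 9.91 ± 2.89 to 37.9 ± 2.76 CPM (adjusted p = 0.0111).

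Single neuronal genes picked from the calls rose, whereas 22 of the 38 genes of the planned neuroendocrine list lay below 0 and that list was not called (camera adjusted p = 0.176). Nptx2 went from 44.2 ± 0.249 to 177 ± 3.70 CPM (adjusted p = 0.00326), Necab1 from 43.9 ± 13.2 to 176 ± 14.9 CPM and Drd2 from 19 ± 0.898 to 64.8 ± 13.3 CPM, while Neurog3 fell from 19.7 ± 6.98 to 4.58 ± 0.715 CPM (adjusted p = 0.0197). The translation repressor gene Eif4ebp1 fell from 79.2 ± 1.53 to 17.9 ± 0.942 CPM (adjusted p = 0.00326), the amino acid transporter genes Slc6a9 and Slc7a3 had log2 fold changes of -2.03 and -1.82, and Slc7a2 rose with a log2 fold change of 1.53. The noncoding RNA gene Rn7sk, whose product holds P-TEFb inactive, had 15.1 and 15 CPM in DMSO and 49.9 and 91.7 CPM in YKL (adjusted p = 0.0112). YKL replicate 2, where it was highest, also had the highest histone share (0.034%) and mitochondrial share (1.78%) of counts. Whether the rise of Rn7sk reflects its transcription or the make-up of the libraries was not tested. Gm38300, an unclassified transcript on chromosome 1 (178339601 to 178341470), rose 27.6-fold to 22.2 ± 2.74 CPM (adjusted p = 0.00202).

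The lower ribosomal protein transcripts did not follow exonic length or GC content. The 630 other genes matched on exonic length had a median log2 fold change of 0.016, and 740 matched on GC content one of -0.002. Exonic length joins all annotated exons of a gene, at a median of 1739 bases for the ribosomal protein genes. It can exceed the length of the mature transcript, so a bias by transcript length was not tested. Reads moving to pseudogenes would have raised these, but 53 ribosomal protein pseudogenes had a median of -0.95. Other transcripts of the 5' terminal oligopyrimidine class, which share translational control with ribosomal proteins, had a median of -0.52, with 23 of 25 below 0 and 5 called lower, namely Eef1a1, Eef1b2, Tpt1, Hnrnpa1 and Gas5. The median of -0.52 would be consistent with a change beyond ribosomal proteins, but the list was chosen and its prediction written after the values were seen, and only the prediction for GC content had been written before.

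Chromosomes 5 and 7 shifted with the replicate number in both groups. The median log2 difference of replicate 2 from replicate 1 on chromosome 5 was -0.39 in DMSO and -0.30 in YKL, with 76.4% of 745 genes lower in both, against 25% by chance, and on chromosome 7 it was 0.23 and 0.29. Across the 20 chromosomes the shifts in DMSO and YKL had a Pearson correlation of 0.955 and, without chromosomes 5 and 7, of 0.893 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give), a test set after the shift was seen. With a trend on GC content and exonic length removed, chromosome 5 still had shifts of -0.45 and -0.25. A copy number difference between the cells behind the 2 replicate numbers could give such shifts, but no DNA data tested it. The labels do not say whether the replicates were separate cultures. Each group holds both replicate numbers, so such a shift adds to the spread within the groups.

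Glycolysis and hypoxia genes stood higher in DMSO replicate 2 than in DMSO replicate 1, with a median log2 difference of 1.98 and 31 of 32 genes above 0, at percentile 100 of 10000 random lists matched on expression, a comparison set after the difference was seen. The difference was 0.03 between the YKL libraries. Hk2 had 4.75 and 164 CPM in the DMSO libraries and 74.2 and 61.7 CPM in the YKL libraries. The difference stayed at 1.97 with the chromosome medians removed. Those medians ran only from -0.39 to 0.23 in DMSO, so this outcome was fixed in advance, and changes of smaller regions were not tested. With a trend on GC content and exonic length removed the difference was 1.93, so such a trend does not explain it. The percentile describes these libraries only. What set the DMSO libraries apart, such as oxygen supply or density if they came from separate cultures, was left open.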
